A study of Homo sapiens with 4 samples.

How the data were processed

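Chromatin of human NCM460 cells was immunoprecipitated with an antibody to CEBPB in 2 samples, and 2 input samples served as controls. Per the labels' protocols, libraries were size-selected between 200 and 500 bp on a gel, amplified by 18 PCR cycles and sequenced as paired 100-base reads on an MGI instrument, with 20 ng of DNA for the inputs. The design text calls the replicates independent experiments. The submitters' processing notes name FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2 and bedtools 2.25.0 and the hg19 build, with no settings. How the inputs were paired with the ChIP samples and whether duplicate reads were removed is not given in the sources used here.

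The files analysed were a peak list for each ChIP sample, called per sample, and a table of the irreproducible discovery rate (IDR) of the pair. In the deposited peak lists each summit has a score, a fold enrichment over background, a −log10 p-value and a −log10 q-value, in the layout of MACS2. Every summit of the authors' lists has a q-value of at most 0.05. The authors' deposited table of the IDR has 20 columns, and all of its 27544 entries have a global IDR of at most 0.05, so no wider threshold could be tried. The interval pairs in its last columns matched intervals of the lists of replicates 1 and 2 in all 27544 entries. They served as keys, and fold and p were taken from the replicate lists; 2 columns of values per sample in the IDR table were not used here. The fold of the authors is used to rank and describe peaks inside each list.

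Fragments were recovered from the deposited fold and −log10 p of each summit. MACS2 adds a pseudocount of 1 to the scaled pileup and to the background before it takes their ratio, and the p-value is the Poisson tail of the pileup over the same background, so that both unknowns can be solved for. With a scale of 0.927 per ChIP read in replicate 1 and 0.800 in replicate 2, the pileup was a whole number of extended reads at 100% of the summits, within a tolerance of 0.005 on the −log10 p. On 8000 simulated summits with known values the step recovered 100% exactly. The background is the input signal in the surroundings of the summit, bounded below by a floor for the genome of 1.00 expected fragments in replicate 1 and 1.36 in replicate 2. Background, in expected fragments, is on the scaled pileup throughout, whereas fragments are counted before scaling. The fold is therefore not the plain ratio of fragments to background, and the scale of the background differs between the replicates. In replicate 1, 11.1% of summits sat at the floor, and in replicate 2, 17.3%. The total read number is not held in the lists. The relative depth of the ChIP samples, 1.57, comes from the floors and scales and assumes equal fragment lengths and genome size.

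The heights had a ceiling. The shortest peaks were 153 bp in replicate 1 and 156 bp in replicate 2, and the largest pileups were 299 and 312 fragments. Reads of one length limited to 1 per position and strand could reach at most 306 and 312. Of the reproducible regions, 7.52% in replicate 1 and 11.9% in replicate 2 lay above 50% of that number, and fold differences among the strongest sites may be compressed, which was not tested.

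Results are for chromosomes 1 to 22 and X unless stated otherwise. Positions are hg19, counted from 1. Chromosome lengths and cytogenetic bands of hg19 came from the band table in the R package circlize 0.4.16. Overlaps of at least 1 bp were computed with bedtools 2.31.1, and chance overlap came from 100 circular shifts. IDR entries with the same interval were merged into distinct regions. Fragments of the replicates were compared per region with exact binomial tests against the running median share of 1001 regions of like height. The test was tested on simulated data for that comparison, with 25602 regions and counting noise only: 99.5% of 200 regions changed 3-fold were recovered, with 11 calls among the unchanged regions. Shares have exact binomial intervals at the 95% level and densities exact Poisson intervals, both of which cover counting error only. Chromosome arms left out centromeric, variable and stalk bands. Density over stain classes and correlations over arms were tested with 100000 permutations, and clustering with 100 random placements of the sites inside their bands. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

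The rule fixed for named sites took the 10 strongest reproducible peaks. Its parts on genes could not be applied: no hg19 sequence or gene annotation was used here, and the gene table at hand is of another build, so no peak is assigned to a gene. For the same reason the planned results on promoter share, C/EBP motifs, sequences at summits, motif and peak strength, promoter against distal motifs, gene lists and genes with a promoter peak were not run. Replicate overlap, rank agreement and the number of reproducible peaks, with their alternatives, were fixed before the data were examined. The comparisons of fragments, chromosomes, bands, clusters, arms and 6p, and the named bands, groups of regions and unshared peaks, were chosen after the data were seen. The inputs entered only through the background in the peak lists, and input libraries of their own were not analysed here.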

Results

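Binding of CEBPB, a basic leucine zipper transcription factor of the C/EBP family, was mapped by ChIP-seq in NCM460, a human colon epithelial cell line. The series held 2 CEBPB ChIP samples and 2 input samples, described as independent experiments, and a peak list was analysed for each ChIP sample. Replicate 1 gave 75169 peaks on chromosomes 1 to 22 and X, which covered 22.3 Mb of the hg19 build, and replicate 2 gave 97829 peaks over 27.8 Mb. Peaks were narrow, with a median width of 253 bp in replicate 1 (quartiles 194 and 349 bp) and 241 bp in replicate 2 (quartiles 191 and 325 bp). The authors' fold enrichment over input had a median of 7.15 in replicate 1 and 6.68 in replicate 2. The median summit rested on 24 extended reads, called fragments here, in replicate 1 and on 28 in replicate 2, over a median input background of 2.00 and 2.18 expected fragments. The ChIP coverage implied by the peak lists was 1.57 times higher in replicate 2 than in replicate 1.

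To ask whether the replicates marked the same sites, the peak lists were intersected with a minimum overlap of 1 bp. In replicate 1, 61602 of 75169 peaks (82.0%, 95% exact binomial interval 81.7 to 82.2%) overlapped a peak of replicate 2, against a mean of 1.94% and a maximum of 2.06% in 100 circular shifts of the peaks along their chromosomes. In replicate 2, 61465 of 97829 peaks (62.8%, interval 62.5 to 63.1%) overlapped a peak of replicate 1, against a mean of 1.48% and a maximum of 1.63% in the shifts. The strongest decile of peaks by fold was shared completely, with 7517 of 7517 peaks in replicate 1 and 9783 of 9783 in replicate 2. Among the weakest decile, 56.3% of replicate 1 peaks and 38.9% of replicate 2 peaks were shared, and in replicate 2 the next deciles were lower still, at 34.4% and 33.8%. Intervals cover counting error over peaks only, and peaks are not independent of each other.

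**Figure D1:**
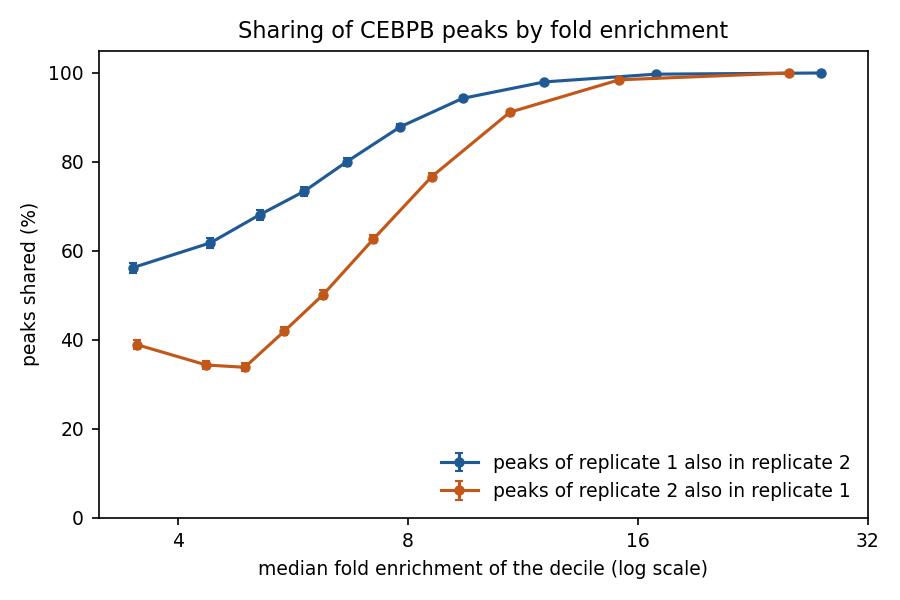
Percent of CEBPB peaks shared with the other replicate (y axis) against the median fold enrichment of each decile of the peaks (x axis, log scale), for replicate 1 in blue and replicate 2 in orange, with 95% exact binomial intervals. Sharing is lowest at 56.3% in the weakest decile of replicate 1 and at 33.8% in a low decile of replicate 2, and it is 100% in the strongest decile of each replicate.

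Peaks seen in 1 replicate only were weak and narrow at the median. By fragments, the tallest of them still reached 97 in replicate 1 and 251 in replicate 2. The 36364 such peaks of replicate 2 had a median fold of 5.17, 19 fragments and a width of 192 bp, whereas shared peaks of the same replicate had 8.93, 40 fragments and 286 bp. The 13567 such peaks of replicate 1 had a median fold of 4.96, 15 fragments and a width of 191 bp, against 8.24, 29 fragments and 271 bp for its shared peaks. By fold, the strongest peak without a partner in replicate 1 lay on chromosome 1 at 7286197 to 7286514 (fold 20.6, 48 fragments). The strongest by fold in replicate 2 lay on chromosome 9 at 120951905 to 120952209 (fold 18.5, 60 fragments). Across 63640 pairs of summits within 100 bp of each other, the fold of the replicates correlated with a Spearman rho of 0.702 (95% bootstrap interval 0.698 to 0.707). The Pearson r of their log2 values was 0.739. These correlations run across sites, which are not independent replicates.

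To define the CEBPB sites that both experiments marked, the authors' deposited table of the irreproducible discovery rate (IDR), which scores how well replicate ranks match, was used. At a global IDR of at most 0.05 the authors' deposited table held 25602 distinct regions on chromosomes 1 to 22 and X. They drew on 25739 intervals of replicate 1 (34.2%) and 25696 of replicate 2 (26.3%). These regions had a median width of 421 bp and covered 12.3 Mb. Their median fold was 15.3 in replicate 1 and 16.0 in replicate 2, with medians of 58 and 76 fragments. The summits of the replicates lay a median of 8 bp apart, and 98.2% lay within 50 bp. The count depended on the definition: an IDR of at most 0.01 in the authors' deposited table left 15504 regions, and 62670 summit pairs had a q-value of at most 0.01 in both replicates with summits within 100 bp.

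The strongest reproducible site lay in band 21q22.12 on chromosome 21 at 36880635 to 36881196, with a fold of 75.7 ± 0.87 (SD, n = 2) and 182 and 220 fragments in replicates 1 and 2. A pair of the 10 strongest sites lay in band 8q24.13 on chromosome 8, at 126442303 to 126442711 with a fold of 74.0 ± 15.1 (SD, n = 2) and at 126244806 to 126245513 with 64.7 ± 20.5 (SD, n = 2). The site in band 6q24.3 on chromosome 6 at 147178577 to 147179122 reached 74.0 ± 2.35 (SD, n = 2). The site in band 7q21.3 on chromosome 7 at 93895456 to 93895983 reached 72.4 ± 19.4 (SD, n = 2), with 86.1 in replicate 1 and 58.7 in replicate 2. Its fragments, before scaling, were 185 and 219. Its background on the scaled pileup was at the floor of 1.00 in replicate 1 and was 2.00 in replicate 2. Sites in 4q32.2 (chromosome 4, 163418713 to 163419200), 14q22.2 (chromosome 14, 55023281 to 55023728) and 1q44 (chromosome 1, 244185526 to 244186032) had mean folds of 67.0, 66.4 and 65.4. Sites in 2p24.3 (chromosome 2, 12596408 to 12597305) and 2q31.2 (chromosome 2, 178029246 to 178029742) had mean folds of 65.0 and 63.9. The input background at these 10 sites was 1.00 to 2.00 expected fragments in replicate 1 and 1.36 to 2.65 in replicate 2. At 6 of these sites the SD between replicates exceeded the whole span of the 10 mean folds, from 63.9 to 75.7, so their rank is not resolved.

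To compare the replicates at the same sites on a scale of counts, the fragments at each of the 25602 reproducible regions were set side by side. The ratio of replicate 2 to replicate 1 fell with height, from a median of 1.46 in the weakest decile of regions (upper quartile 1.79) to 1.14 in the strongest decile (quartiles 1.06 and 1.23). The strongest decile had medians of 171 and 198 fragments, under ceilings of 306 and 312. Such a ceiling would narrow differences among tall regions, and its part in the fall was not tested. Against the median share among regions of like height, 749 regions (2.93%) differed between the libraries by more than counting noise, 313 with more fragments in replicate 2 and 436 with more in replicate 1 (two-sided exact binomial tests, adjusted p at most 0.05 by the Benjamini-Hochberg method). Beyond counting noise, the replicates varied with a coefficient of variation of 13.5%. The same estimate gave 7.1% on the simulated data with counting noise and 200 changed regions. A small number of regions can therefore account for part of the 13.5% variation. The p-values cover counting error only and leave out that variation, so the 749 calls include ordinary spread between replicates. The tests compare the libraries and not conditions, and the regions had been selected for agreement of rank. Among regions at an IDR of at most 0.01 the number was 368.

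**Figure D2:**
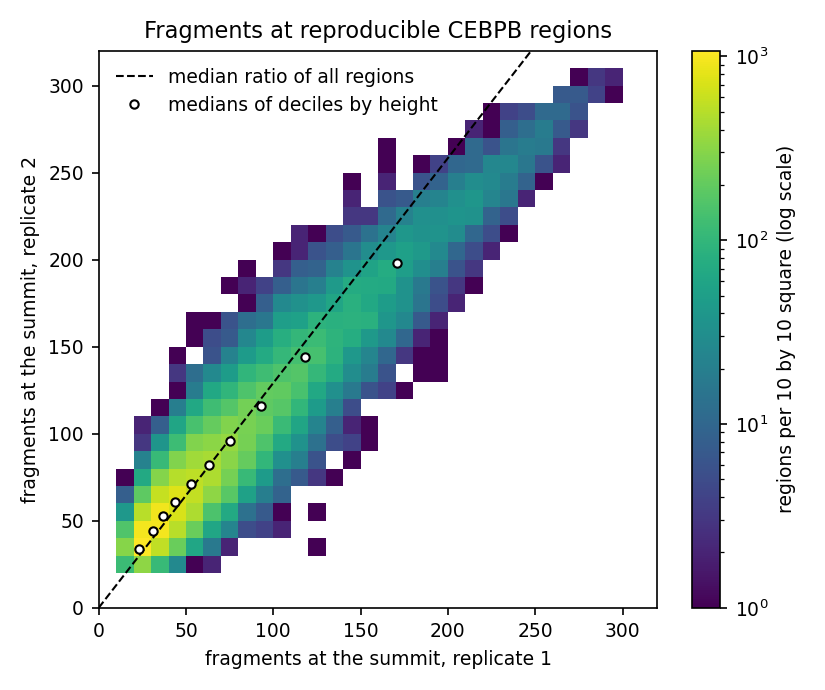
Number of reproducible CEBPB regions in squares of 10 by 10 fragments (colour, log scale), by the fragments at the summit in replicate 1 (x axis) and replicate 2 (y axis). White points are medians of deciles by height and the dashed line is the median ratio of all regions, 1.29. The points bend below the line as the ratio falls from 1.46 to 1.14. The part of the ceiling on heights in this was not tested.

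To describe where in the genome CEBPB bound, reproducible regions were counted per chromosome and cytogenetic band. Over chromosomes 1 to 22 and X the density was 8.43 regions per Mb. Chromosome 17 was the densest with 13.8 regions per Mb (1124 regions), followed by chromosome 19 with 11.6 (95% Poisson interval 10.7 to 12.5), chromosome 12 with 10.3 (9.80 to 10.9) and chromosome 20 with 10.2 (644 regions). The lowest densities were 4.68 on X (4.35 to 5.04), 5.37 on chromosome 13 (4.96 to 5.82), 5.80 on chromosome 4 (5.46 to 6.15) and 5.93 on chromosome 18 (5.40 to 6.50). These are densities over the full length, and the order depends on that: chromosomes 13, 14, 15 and 22 count short arms without a reproducible region, and their long arms, without centromeric and variable bands, had 6.47, 10.7, 10.1 and 12.9 regions per Mb. Sites cluster, so these intervals are too narrow for a comparison of chromosomes as such.

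**Figure D3:**
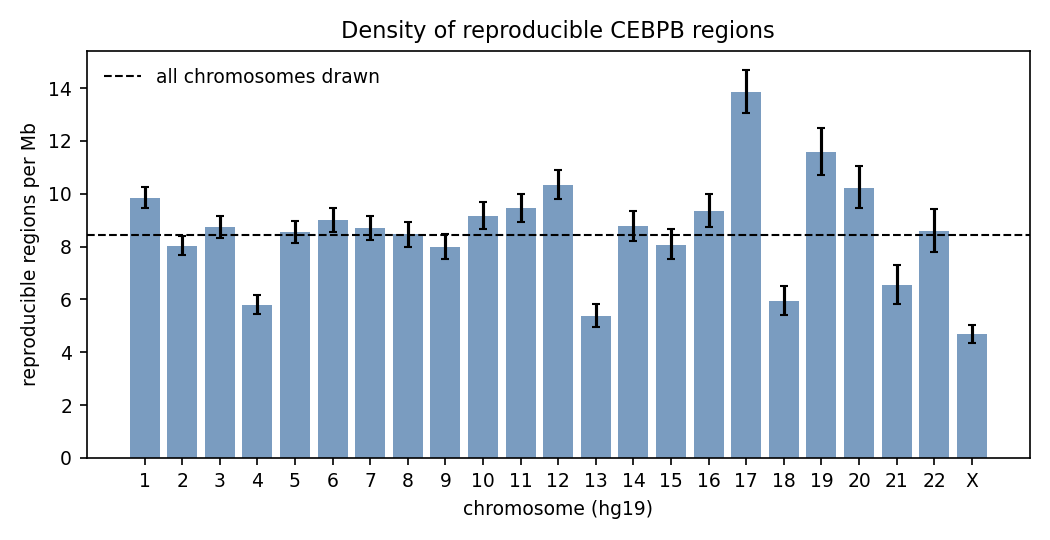
Reproducible CEBPB regions per Mb (y axis) on each chromosome (x axis, hg19), with 95% Poisson intervals and the density over all of them, 8.43, as a dashed line. Chromosome 17 stands highest at 13.8 and X lowest at 4.68.

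Among bands of at least 2 Mb, 20q13.13, which carries the CEBPB gene itself, had the highest density with 94 regions in 3.4 Mb, or 27.6 per Mb (95% Poisson interval 22.3 to 33.8). Band 11q13.1 followed with 26.4 (20.4 to 33.6), then 9q34.11 with 80 regions in 3.2 Mb (19.8 to 31.1 per Mb), 17q21.2, home of the type I keratin gene cluster, with 24.4 (18.7 to 31.3), and 9q31.3 with 23.9 (19.1 to 29.5). The intervals of these 5 bands overlap. Their arms had input backgrounds at peaks above the median arm (1.35 times on 20q, 1.24 on 9q, 1.19 on 17q and 1.07 on 11q). Densities of bands and chromosomes were not adjusted for this. Giemsa-negative bands, which are rich in genes, held 13566 regions at 10.5 per Mb, and the lightest Giemsa-positive bands held 2459 at 11.3 per Mb. The density was 8.87 and 7.55 in the next darker classes and 5.71 in the darkest bands (2844 regions). The ratio of Giemsa-negative to darkest bands was 1.85 (two-sided permutation test of the stain labels over bands, p = 1e-05, the smallest that 100000 permutations can give). Centromeric bands held 67 regions at 0.65 per Mb, and much of their sequence is not assembled or not uniquely mappable.

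To ask whether CEBPB sites lay near each other, neighbours within 12.5 kb were counted. Of the reproducible regions, 39.6% had another within 12.5 kb, against a mean of 24.3% and a maximum of 25.4% when sites were placed at random inside their own bands 100 times. Groups of at least 5 regions, each within 12.5 kb of the next, numbered 125 and held 689 regions. The 3 largest groups held 9 regions each, in 12q24.31 (chromosome 12, 123376401 to 123431747, mean fold 18.7 ± 6.33, SD over regions), 14q23.1 (chromosome 14, 61979126 to 62037027, mean fold 16.3 ± 5.13) and 11q13.1 (chromosome 11, 65239554 to 65281373, mean fold 15.6 ± 5.35). Groups of 8 regions lay in 3p24.1 (chromosome 3, 30638659 to 30686457) and 1p22.1 (chromosome 1, 92329634 to 92366606), with mean folds of 21.9 and 21.6. Regions with a neighbour were hardly stronger than the rest: their median fold was 16.1 (10147 regions) against 15.6 (15455 regions), a difference in mean log2 fold of 0.03 (two-sided permutation test, p = 0.00012). Regions of the same group are not independent, so this p-value may be too small.

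The input background at the peaks differed between chromosome arms in the same way in both replicates. The mean background at summits was 4.52 expected fragments on 5p in replicate 1 and 4.70 in replicate 2, and 1.57 and 1.72 on 18q. Relative to the median arm, 5p stood at 1.74, 12p at 1.41, 20q at 1.35 and 14q at 1.33, and 18q at 0.619, 4q at 0.734 and 13q at 0.749. Across 41 arms the backgrounds of the replicates correlated with r = 0.996 and rho = 0.993 (permutation p = 1e-05 for each, the smallest possible, adjusted p of 2.3e-05 and 1.2e-05 over 7 relations). Arms with more background also held more reproducible regions per Mb (r = 0.479, permutation p = 0.0016, adjusted p = 0.0023; rho = 0.689, p = 1e-05, adjusted p = 1.2e-05). Without 5p and 12p, the arms farthest from the median, r was 0.627. Arms of one genome are not independent samples, and 5p itself held 7.94 regions per Mb, below the density over all chromosomes.

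**Figure D4:**
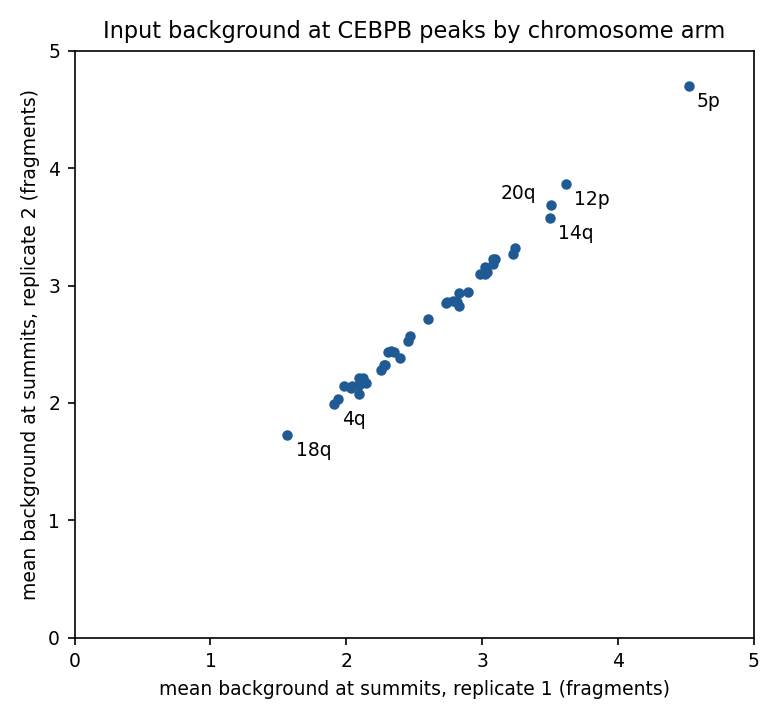
Mean input background at CEBPB peak summits on each of 41 chromosome arms, in replicate 1 (x axis) and replicate 2 (y axis). Values are expected fragments on the scaled pileup of each replicate, and each point is 1 arm. Arm 5p stands highest at 4.52 and 4.70 and 18q lowest at 1.57 and 1.72.

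On the short arm of chromosome 6, the bands 6p21.33 and 6p21.32, which carry genes of the major histocompatibility complex, held 24 reproducible regions in 3.1 Mb, or 7.74 per Mb (95% Poisson interval 4.96 to 11.5). The other bands of the arm held 12.0 per Mb (11.1 to 12.9), and the intervals overlapped. The difference was not tested. In replicate 1, 65.5% of 58 summits in these bands had the lowest background that the peak caller assigns, against 6.94% of 2132 summits in the rest of the arm. In replicate 2 the shares were 70.0% of 60 summits and 10.4% of 2734 summits. Density alone did not set these bands apart: 6p21.33 had 10.0 regions per Mb and 6p21.32 had 5.00, while 6p12.3, of the darkest stain class, had 6.07. In 6p12.3, 29.0% and 41.6% of summits sat at the floor in replicates 1 and 2. Band 6p22.1, which borders 6p21.33 and also carries genes of the complex, had 5.88 regions per Mb with 14.7% and 15.7% of summits at the floor.

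**Figure D5:**
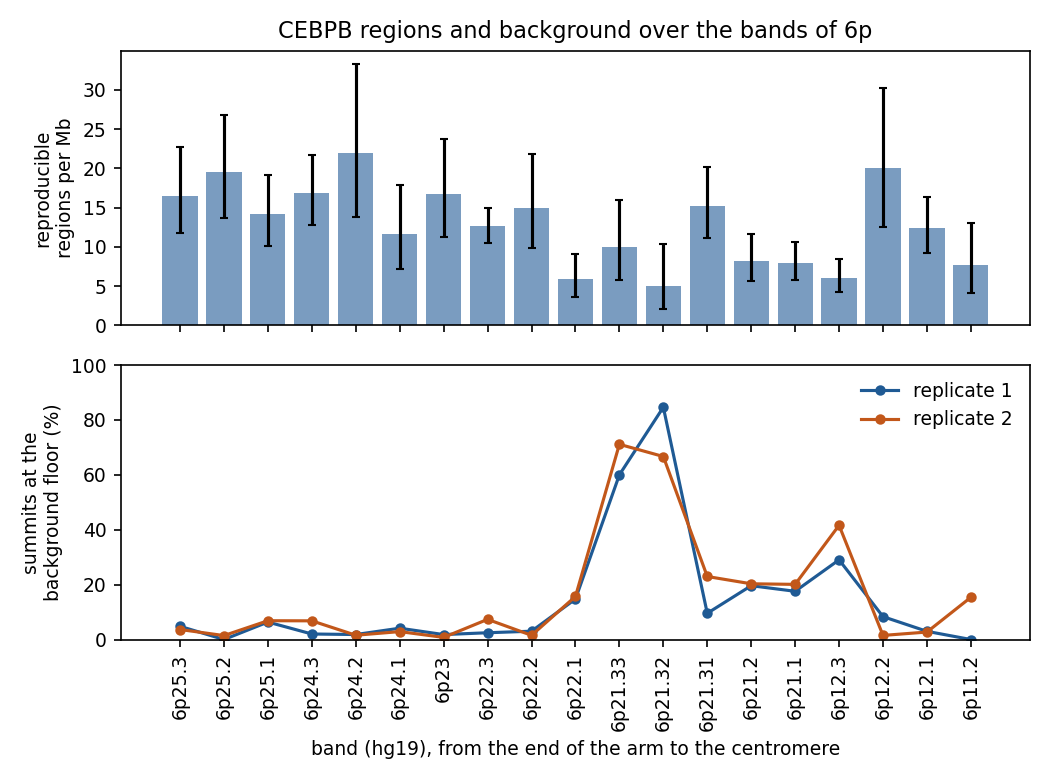
Reproducible CEBPB regions per Mb with 95% Poisson intervals (upper panel) and percent of peak summits at the lowest background in replicate 1 (blue) and replicate 2 (orange, lower panel), over the bands of the short arm of chromosome 6 (x axis, hg19). Bands 6p21.33 and 6p21.32 stand out with 60.0% and 84.6% of replicate 1 summits at the floor.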

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

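The 3 results of this part lie outside chromosomes 1 to 22 and X and were found after the data were seen. Sequences outside these chromosomes, which entered few of the other results, held peaks called over input. The 7 alternative haplotype sequences of chromosome 6 held 144 reproducible regions, with medians of 36.5 fragments in replicate 1 and 42 in replicate 2. They are alternative versions of the same part of the chromosome, so these are not 144 separate sites. The alternative haplotype sequence of chromosome 17 held 12 regions, with medians of 32.5 and 50.5 fragments. The unplaced sequence gl000225 held 4 reproducible regions but 102 summits in replicate 1 and 161 in replicate 2, over a median background of 10.0 expected fragments in replicate 1, against 2.00 on the chromosomes.

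The pattern weighed here is the number of sites in bands 6p21.33 and 6p21.32 of the major histocompatibility complex, and both of its tests were chosen after the result was seen. At 7.74 per Mb it was low for the arm, but the difference was not tested, and overlap of the intervals does not decide it. Band 6p12.3, outside the complex, was lower at 6.07, but it is of the darkest stain class and so not a like band. Band 6p22.1, which also carries genes of the complex, had 5.88 and was counted with the rest of the arm. A deficit is therefore neither established nor excluded. A loss of both copies of the complex in this cell line is argued against by the 144 regions on its alternative haplotype sequences. What stays open is that reads matching several haplotypes equally well were spread or dropped, which the summits at the background floor, at least 65.5% in these bands in each replicate, are consistent with. No other biological explanation was tested.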

How the results depend on the processing

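The alternatives for bands, clusters, arms and fragment differences, the rank agreement inside the IDR table and the overlap over all sequences were chosen after seeing the data. In the 5 alternative overlap settings tried, sharing stayed far above the shifts, at 76.9 to 83.1% for replicate 1 and 59.1 to 64.0% for replicate 2. The rank agreement of 0.702 became 0.786 with −log10 p, 0.691 at a −log10 q of at least 5 and 0.601 inside the IDR table, the last over fewer and stronger sites; the cause was not tested. The 25602 reproducible regions became 15504 at an IDR of at most 0.01 and 62670 pairs under the rule of q-value and summit distance, which asks for no match of rank; an IDR of 0.1 gave no value. The 749 regions that differed became 368 at an IDR of at most 0.01, with 15504 regions tested. The stain ratio of 1.85, the clustering of 39.6% and the arm correlation of 0.689 kept their side of the test in all settings run for them. Leaving out a replicate gave stain ratios of 1.83 to 1.95 and clustering of 42.6 to 44.1%. All alternatives of the promoter, motif, 8-mer and gene results were not run. No paired analysis was possible because the inputs enter only through the peak caller's background and no groups were tested against each other. Counts are low at the unshared peaks, with medians of 15 and 19 fragments, and the ceiling may limit the strong ones.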

Other observations

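Of the tests in this part, those of base composition, copy number and the thinning of all peaks were fixed before their results were seen, and those of chance variation, the strongest summits, peak widths and the ceiling after.

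Replicate 2 had more peaks than replicate 1. Over all sequences, replicate 2 was thinned to the coverage of replicate 1, which had 81303 summits. After thinning, 99536 summits of replicate 2 still passed the weakest p-value in the list of replicate 1. Whether these thinned peaks would still be called was not tested, so the count does not decide whether depth was the whole cause. Among peaks of replicate 2, 89.8% of unshared and 97.9% of shared ones passed that p-value. Unshared peaks were picked for their absence in replicate 1, so their share does not decide whether they were too shallow there. For stronger summits depth may account for the surplus or more: with thinning that allowed for the ceiling, replicate 2 had 0.979 times the summits of replicate 1 at a −log10 p of at least 20 and 0.904 times at 50, 56963 against 54447 summits at 10, but 1.16 times as many at 5. Stacks of few original fragments stay open, since unshared peaks were narrower than shared ones at all 19 heights from 12 to 30 fragments (differences of −11.3 bp in replicate 1 and −17.0 bp in replicate 2), as weak true sites might also be. In a later test on exact PCR copies, no summit exceeded what 1 read per position and strand allows. The tallest stood at 97.7% of it in replicate 1 and 100% in replicate 2, so taller stacks of copies are argued against. Unshared peaks reached at most 97 fragments in replicate 1 (31.7% of that number) and 251 in replicate 2 (80.45%). For stacks of such heights the test decides nothing, since the handling of duplicate reads is not given. No biological explanation was tested.

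The input background at peaks differed between chromosome arms. Base composition, as far as stain classes capture it, is argued against as the whole cause by the ratio of 5p to 18q. That ratio was at least 2.61 inside Giemsa-negative and inside the darkest bands. These arms had the highest and lowest background, and base composition itself was not measured, so differences of composition within a stain class are not excluded. Chance variation of an input library is argued against by the correlation of 0.996 between replicates, whose background floors of 1.00 and 1.36 differ, so that they were not given identical input reads. Copy number differences of the cell line are a candidate explanation, since arms kept their order between Giemsa-negative and Giemsa-positive bands (rho of at least 0.939 in each replicate). No count of chromosome copies was analysed here, and a link with the density of CEBPB sites was not separated from the power to call peaks on arms with more DNA.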
